A study of Mus musculus with 375 samples.

How the data were processed

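Single cells sorted by flow cytometry as Lgr5-positive from the small intestine of mice on a control diet or a high-fat diet (HFD) were sequenced by Smart-seq2, a plate-based method that makes full-length cDNA from one cell per well. The titles place the cells in 4 sets, control 1, control 2, HFD 1 and HFD 2, with 94, 94, 93 and 94 cells. The deposited values are TPM, 1 value per gene and cell. Per the submitters' processing notes, reads were handled with Bowtie2 and RSEM against the mouse build mm10, and tool versions and the gene annotation are not given in the sources used here. Each cell's values summed to between 999999.2 and 1000000.6. TPM keeps no read depth, so the depth behind each value is unknown. The table held 23420 genes, of which 4327 were listed at 0 in every cell, and 4 symbols had been turned into dates. No symbol began with the prefix of mitochondrially encoded genes, so the list of those genes fixed beforehand could not be measured. Of the symbols, 21751 (92.9%) were found in GENCODE M21, the source of the coordinates, which are on GRCm38 (mm10) and 1-based.

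Cells with fewer than 2000 genes above TPM 0 were left out. These were 8 cells (1, 3, 2 and 2 in control 1, control 2, HFD 1 and HFD 2), and 367 passed (93, 91, 91 and 92). The set was the unit of replication, with 2 sets per diet, because cells of one set are not independent. The labels do not say whether the sets are separate mice, so p-values cover only these sets, whose spread may be technical. TPM was averaged over the passing cells of a set. The test was limma with a mean-variance trend on log2(mean TPM + 1) for genes with a mean of at least 1 TPM, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are HFD over control on that log2 scale, which understates changes of low genes. The same fit was run on the stem-like and progenitor-like cells alone, and limma without a trend on each set's stem-like minus progenitor-like log2 values tested whether the diet difference differed between these classes.

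Gene lists were fixed before the data were examined, as were the cell type markers, the main tests, the other settings to be tried and the rule for named genes. The 25 lists covered MHC class II antigen presentation and its transcription factors, MHC class I, interferon gamma and type I interferon responses, co-stimulatory ligands, pattern recognition, antimicrobial products, stem cell signature, Wnt targets, Notch, PPAR targets and fatty acid oxidation, ketogenesis, cholesterol synthesis, fatty acid synthesis, glycolysis, the nuclear-encoded and mitochondrially encoded respiratory chain, ribosomal proteins, S phase, G2/M phase, immediate early and heat shock genes, the unfolded protein response, antioxidant genes and housekeeping genes. None was chosen on these samples, although MHC class II is the subject of the series title. Lists were tested with limma's camera with a preset correlation of 0.01, with camera's estimated correlation and with fry beside it. Camera compares a list with the other genes, whereas fry tests a list against no change. The text names, per comparison, the 10 largest called rises and 10 largest called falls whose sets did not overlap, all tested genes of the MHC class II list, genes fixed by name such as Lgr5, Ascl2, Olfm4, Cpt1a and Pdk4, and up to 4 members of each list discussed with the smallest p. Further called members of a list are named where a count needs them. Predicted genes, pseudogenes and a few others that the rule covers were counted and not named.

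Numbers of list genes in the text count those that passed the filter on low genes. Per-cell scores are the mean log2(TPM + 1) of all of a list's genes in the table, averaged over the cells of a set. Differences of scores and of shares were compared with the spread between sets, the SD pooled over both diets, and with an exact two-sided permutation of the 4 sets, whose smallest possible p is 0.333. A cell counted as holding a transcript at 1 TPM or more. Shares carry 95% Clopper-Pearson intervals, and a share of 0 carries the limit that 3 cells of the total would set; both cover counting error only. Clusters came from scanpy's Leiden method on log2(TPM + 1) of 2000 variable genes, with 20 principal components, 15 neighbours and resolution 1. A cluster took the name of the class whose markers stood highest above the other cells, among classes with at least 3 markers detected in 25% of its cells; this naming rule was chosen after seeing the data. No doublet caller was run, since the cells were sorted into wells.

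The limma and camera steps were tested on simulated set values for 200 changed genes over 5 runs. For all cells (11667 genes), 19.4% of genes changed by log2 1 and 85.8% of those changed by log2 2 were recovered, 4.23% of calls were false, and no call had the wrong sign. For stem-like and progenitor-like cells (11622 genes) the shares were 19.2%, 82.6% and 3.93%. The simulated genes varied independently, with variances drawn from limma's own fit to these data. Deviations shared between genes of a set were not simulated. The false share thus checks the steps and is not the error rate of the real calls. The other settings, fixed beforehand, covered the replicate number as a block, leaving out each set, the pseudocount, the filters on genes and cells, the summary over cells, the scaling, the trend, the cell classes, the list test and the clustering. Chosen after seeing the data were TPM rescaled without Rn45s, the 45S ribosomal RNA precursor, which took a large and unequal share of TPM, and several class-wise and scaling alternatives for lists and scores. The software was Python 3.11.15 with scanpy 1.11.5, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1.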

Results

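The series asked, by its title, whether a high-fat diet lowers MHC class II expression in the intestinal epithelium. The data were single-cell transcriptomes of cells sorted for Lgr5, the marker of crypt base stem cells of the small intestine, in 2 sets from mice on a control diet (94 and 94 cells) and 2 sets from mice on a high-fat diet (HFD; 93 and 94 cells). After the filter on genes per cell, 93, 91, 91 and 92 cells entered the comparisons from control 1, control 2, HFD 1 and HFD 2. Medians of 6895, 6130, 6857 and 6348.5 genes per cell were detected in them. Over all cells the HFD median lay 81 genes above that of the control sets, within the spread between sets of 485. The ribosomal RNA precursor Rn45s took 39.1%, 24.6%, 26.9% and 18.6% of TPM, a difference of −9.16 percentage points between the diets with a spread of 8.38. The median log2 fold change of all tested genes was 0.13 with TPM as deposited and −0.05 with Rn45s left out of the total, so list medians are given relative to that of all genes.

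MHC class II transcripts were lower in the HFD cells. Cd74, the invariant chain that accompanies class II molecules, averaged 478 ± 23.7 TPM in the control sets and 183.96 ± 20.2 TPM in the HFD sets (SD, n = 2 each), a log2 fold change of −1.38 (SE 0.26). H2-Aa, which encodes an alpha chain of the class II dimer, fell from 195.13 ± 26.4 to 51.4 ± 32.8 TPM (log2 −2.06, SE 0.32, limma adjusted p = 0.000704). Of the 7 members of the class II list that passed the filter on low genes, 6 fell: H2-Aa, H2-Ab1 (−1.57, SE 0.29), H2-DMb1 (−1.55, SE 0.29), H2-Eb1 (−1.49, SE 0.28), Cd74 and H2-DMa (−1.31, SE 0.25). Ciita, the transcriptional co-activator that switches class II genes on, had a log2 fold change of −0.99 (SE 0.36) and did not pass over all genes (adjusted p = 0.300). All 7 passed when adjusted over the list alone. The list's median lay −1.62 from that of all genes (camera adjusted p = 1.86e-20), with an adjusted p = 0.211 with an estimated correlation. The H2 genes lie together on chromosome 17, between H2-DMa (34119541 to 34139101) and H2-Eb1 (34305867 to 34316674), while Cd74 lies on chromosome 18 (60803848 to 60812652) and Ciita on chromosome 16 (10480059 to 10528418). With Rn45s left out of the total, none of the 7 passed over all genes although the median was −1.61 relative to all genes; H2-Aa then had a fold change of −2.22 (SE 0.34, adjusted p = 0.111). Without the set HFD 1, 1 of the 7 passed over all genes.

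**Figure D1:**
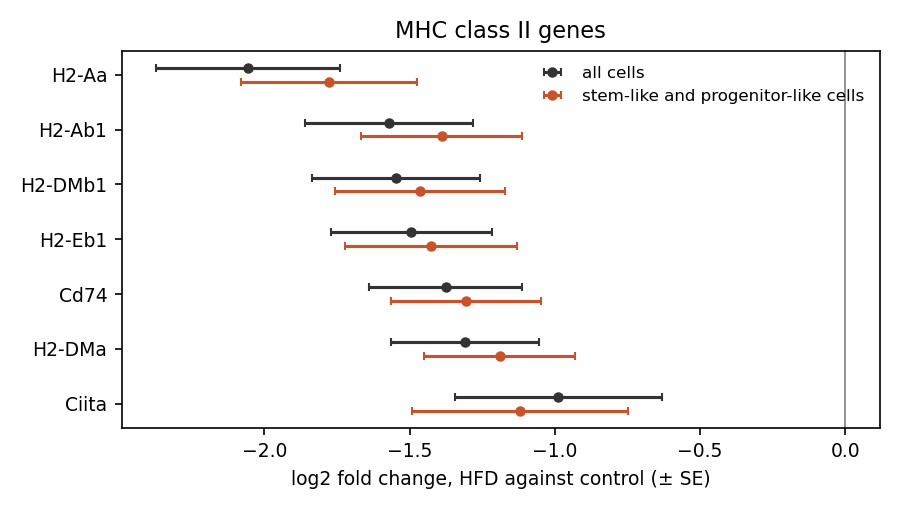
Log2 fold changes (HFD over control, with standard errors) of the 7 tested MHC class II genes over all passing cells and over stem-like and progenitor-like cells alone. Values range from −2.06 for H2-Aa to −0.99 for Ciita over all cells, and all lie below 0.

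Fewer cells held class II transcripts on the HFD. Cd74 was at 1 TPM or more in 97.8% (95% interval 92.4 to 99.7%) and 90.1% (82.1 to 95.4%) of control cells and in 50.5% (39.9 to 61.2%) and 55.4% (44.7 to 65.8%) of HFD cells. H2-Ab1 was found in 88.2% and 74.7% of control cells and in 38.5% and 41.3% of HFD cells. H2-Aa was found in 60.2% and 58.2% against 15.4% and 27.2%, and Ciita in 48.4% and 31.9% against 13.2% and 20.7%. Averaged over Cd74, H2-Ab1, H2-Aa, H2-Eb1 and Ciita, the share was lower by 38.7 percentage points, written as a difference of −38.7 with a spread of 6.23. In cells that held a transcript, the mean log2 TPM of these 5 genes differed by −0.42 with a spread of 0.27. The per-cell class II score was 3.04 and 2.82 in the control sets and 1.11 and 1.37 in the HFD sets, a difference of −1.69 with a spread of 0.17. For each of these measures the exact permutation p was 0.333, the smallest that 4 sets allow. Ptprc, the leukocyte marker CD45, was at 1 TPM or more in 0 of 93, 0 of 91, 0 of 91 and 1 of 92 cells, and 0 of 93 and 0 of 91 allow shares of up to 3.23% and 3.30%.

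**Figure D2:**
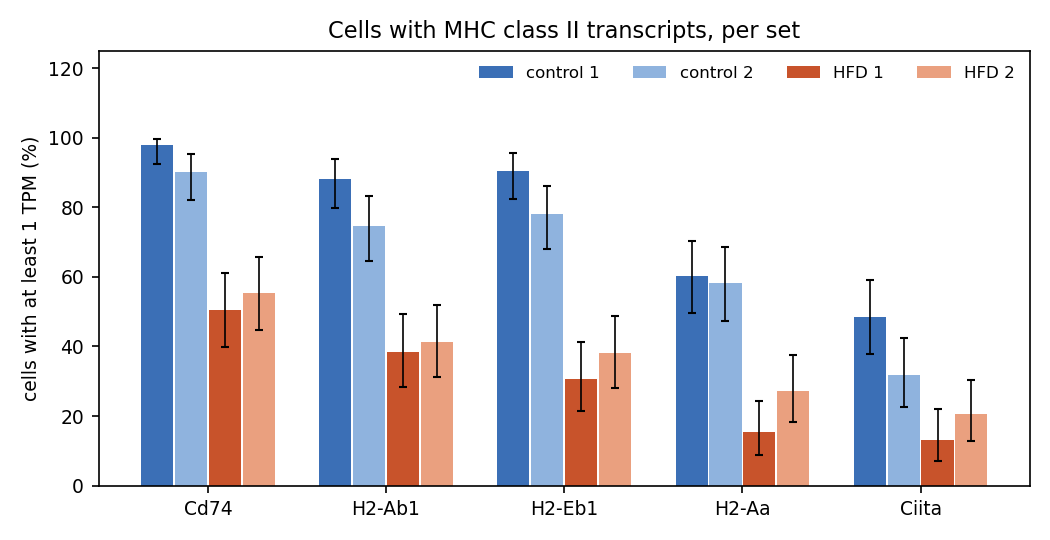
Percent of passing cells of each set with at least 1 TPM of Cd74, H2-Ab1, H2-Eb1, H2-Aa and Ciita, with 95% Clopper-Pearson intervals (counting error only). For Cd74 the control sets stand at 97.8% and 90.1% and the HFD sets at 50.5% and 55.4%.

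Across all genes, the largest rises in HFD cells were in transcripts of Paneth cells, the secretory neighbours of crypt stem cells, and the largest falls were in Reg3b and Reg3g. Defa24, an alpha-defensin, averaged 14.1 and 12.1 TPM in the control sets and 2400 and 197.41 TPM in the HFD sets (log2 fold change 5.62, SE 0.58). That SE is limma's moderated one and does not reflect how far the 2 HFD sets lie apart. Defa24 was at 1 TPM or more in 14, 14, 27 and 25 cells of control 1, control 2, HFD 1 and HFD 2. In stem-like and progenitor-like cells alone it averaged 11.7, 13.1, 23.6 and 54.5 TPM. Itln1, a carbohydrate-binding lectin, rose by 4.13 (SE 0.33) and Lyz1, the Paneth cell lysozyme, by 4.01 (SE 0.39). Reg3b and Reg3g encode antimicrobial lectins. Reg3b went from 217.46 and 83.7 TPM in the control sets to 0.355 TPM in HFD 1 and is listed at 0 in HFD 2 (−6.87, SE 0.38), on transcripts in 12, 4, 1 and 0 cells. Reg3g fell by 2.54 on the log2 scale (SE 0.32), from 247.09 ± 132.63 to 40.6 ± 17.9 TPM.

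In all, limma called 59 of 11667 genes, 43 higher and 16 lower in HFD cells; by median-ratio scaling of the sets the split was 30 higher and 20 lower, and with cell-wise logs and Rn45s left out of the total it was 12 higher and 21 lower. Both HFD sets lay beyond both control sets for each of the 59, as they did for 4878 of the tested genes (41.8%), where chance gives 1 in 3 splits. Among the genes that rose, 10 carry Defa names. Other large rises were Defa17 (6.83), Defa23 (5.58), Defa21 (4.65), Defa22 (4.55), Defa5 (4.26), the defensin-like gene AY761184 (4.25) and Defa3 (4.16). These copies lie close together on chromosome 8 where placed, share reads and are uncertain one by one, and most of their level came from HFD 1 (Defa17 was at 1516 TPM there and at 46.1 TPM in HFD 2). Beside the Reg3 genes and the class II genes H2-Aa and H2-Ab1, the largest falls were in H2-Q8 (−2.50, SE 0.47), a class I gene of a family of close copies, S100g (−2.49, SE 0.41), a calcium-binding protein, Oplah (−2.19), Nrn1 (−1.93), Tk2 (−1.67), the mitochondrial thymidine kinase, and Mir192 (−1.57). H2-Q8 was low, at 6.37 and 7.84 TPM in the control sets, listed at 0 in HFD 1 and at 1.04 TPM in HFD 2. Of the 12 tested antimicrobial products, Lyz1 rose, Reg3b and Reg3g fell and 9 did not pass, and adjusted over the list alone 2 rose and 3 fell (list adjusted p = 0.0574, 0.587 with an estimated correlation). The Paneth marker score stood 0.69 higher in the HFD sets (spread 0.083). The count of 59 became 6 with Rn45s left out of the total and 0 by limma with no filter on low genes, where 1398 had an unadjusted p under 0.05.

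Fabp1 and a few other lipid genes were higher in HFD cells. Fabp1, the liver-type fatty acid binding protein and a PPAR target, rose from 39.8 ± 17.2 to 416 ± 61.2 TPM (log2 fold change 3.41, SE 0.28, limma adjusted p = 3.50e-08). Sqle, squalene epoxidase of the cholesterol pathway, rose from 9.56 ± 2.02 to 27.5 ± 4.08 TPM (1.44, SE 0.30), and Sc4mol, a sterol methyl oxidase, rose by 1.47 (SE 0.33). Of 50 PPAR targets and fatty acid oxidation genes, Fabp1 and Acaa1b (2.13, SE 0.46), a peroxisomal thiolase, rose and 48 did not pass, with 4 rising when adjusted over the list alone. That list's median lay 0.14 above that of all genes (camera adjusted p = 0.00879, 0.741 with an estimated correlation), and the call was lost without control 1 or without HFD 2 (adjusted p = 0.189 and 0.204). Mgll had a fold change of 2.02 and an adjusted p = 0.0535, and Fabp2 had 0.998 and 0.190. Of 25 cholesterol synthesis genes, Sqle and Sc4mol rose and 23 did not pass, with 10 rising over the list alone (median 0.33 above all genes, camera adjusted p = 2.45e-07, 0.211 with an estimated correlation). Fdps, at 1.27, had an adjusted p = 0.0502. Enterocyte markers, of which Fabp1 and Fabp2 are members, scored 0.59 higher in the HFD sets (spread 0.126), and 0.659 higher within stem-like and progenitor-like cells. Of the 6 ketogenesis genes none passed, although 2 rose when adjusted over the list alone, and the list had an adjusted p = 0.0618 (0.694 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, and Pdk4 had values of 0.10 (SE 0.24) and −0.03 (SE 0.35) and did not pass. Neither list of the remaining carbon metabolism was called. Of 17 fatty acid synthesis genes none passed (adjusted p = 0.623), nor did any of 16 glycolysis genes (0.0618), among them Ldha at 0.77 and Pkm at 0.74.

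The unfolded protein response and S phase lists were called higher by camera with its preset correlation, although few of their genes passed. Of 22 unfolded protein response genes, the chaperones Calr (1.12, SE 0.26) and Sdf2l1 (1.17, SE 0.26) rose and 20 did not pass, with 9 rising over the list alone. That list's median lay 0.54 above all genes (camera adjusted p = 2.52e-07, 0.211 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 105.65 ± 3.05 to 212.18 ± 13.7 TPM (0.998, SE 0.24) and missed the threshold (adjusted p = 0.0721). Hsph1 (1.29, SE 0.25) rose among 22 immediate early and heat shock genes, with 3 rising over the list alone (list adjusted p = 0.121). None of 40 S phase genes passed over all genes and 11 rose over the list alone, with the median 0.43 above all genes (camera adjusted p = 3.46e-12, 0.362 with an estimated correlation). Pcna, the polymerase clamp, averaged 166.46 ± 4.14 and 328.28 ± 9.87 TPM (0.98, SE 0.25, adjusted p = 0.104). Per cell, the S phase score was 3.33 and 3.06 in the control sets and 4.04 and 3.93 in the HFD sets, a difference of 0.78 with a spread of 0.15. The G2/M score differed by 0.23 with a spread of 0.22, and none of 52 G2/M genes passed (list adjusted p = 0.349). Exact permutation gave p = 0.333 for S phase, the smallest possible, and 0.667 for G2/M. Of 46 nuclear-encoded respiratory chain genes none passed and 1 rose over the list alone; the list was called higher (median 0.28 above all genes, camera adjusted p = 6.88e-07, 0.741 with an estimated correlation), a call lost without control 1 or HFD 2 (adjusted p = 0.250 and 0.168).

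**Figure D3:**
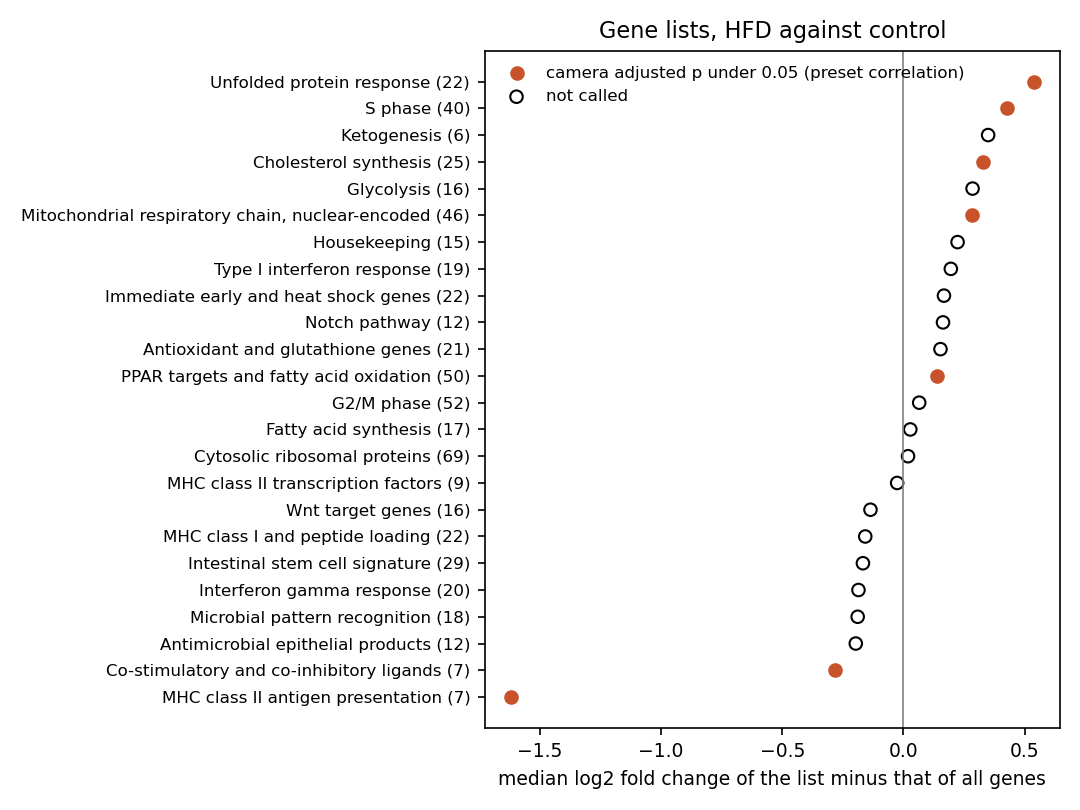
Median log2 fold change (HFD over control) of each measured gene list minus that of all genes, over all passing cells, with the number of tested genes in brackets. Filled points mark the 7 lists called by camera with its preset correlation, from −1.62 for MHC class II antigen presentation to 0.54 for the unfolded protein response, and none of these calls held with an estimated correlation.

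Few genes passed among the stem cell, Wnt, Notch and other immune lists. Lgr5 averaged 142.07 ± 32.7 and 134.37 ± 2.57 TPM (−0.06, SE 0.25), Ascl2 had a log2 fold change of 0.35 (SE 0.24) and Olfm4 of 0.39 (SE 0.74), and none passed. Of 29 stem cell signature genes Nrn1 fell and 28 did not pass (list adjusted p = 0.0574), and of 16 Wnt targets none passed (0.340). Of 12 Notch genes none passed, with 1, Hes6 (0.95, SE 0.24, chosen by its p), rising over the list alone (list adjusted p = 0.417). Among 7 co-stimulatory and co-inhibitory ligands, Sectm1b fell from 72.2 ± 11.8 to 26.955 ± 0.0483 TPM (−1.38, SE 0.25) and 6 did not pass; the list was called lower (camera adjusted p = 0.0388, 0.587 with an estimated correlation), and not without control 1 (0.189) or HFD 2 (0.252). None of 20 interferon gamma response genes passed, with 1 falling over the list alone (Tgtp2, −1.51, SE 0.43; list adjusted p = 0.121). No gene passed among 19 of the type I interferon response (0.417), 18 of pattern recognition (0.349), 9 class II transcription factors (0.983), 21 antioxidant genes (0.340) and 15 housekeeping genes (0.340). Of 22 MHC class I and peptide loading genes Calr rose and 21 did not pass (0.623), with the median −0.16 from that of all genes. Not taken relative to all genes, that list's median was −0.03 and its mean 0.07. Rpl34 (1.23, SE 0.25) rose among 69 ribosomal protein genes (0.966).

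Clusters gave stem-like, proliferating progenitor-like, goblet-like and Paneth-like cells. In the progenitor-like clusters, stem markers averaged log2(TPM + 1) of 6.48, 6.68, 6.53 and 6.75. The cells outside each cluster had 6.74, 6.69, 6.70 and 6.68. Markers of proliferation named these clusters, so the name does not tell progenitors from cycling stem cells. Stem-like cells made up 49.5% and 49.5% of the control sets and 30.8% and 41.3% of the HFD sets, and progenitor-like cells 44.1% and 42.9% against 52.7% and 45.7%. Goblet-like cells were 5.38% and 7.69% against 7.69% and 6.52%. Paneth-like cells were 1 of 93 and 0 of 91 control cells, where 0 of 91 allows a share of up to 3.30%, and 8 of 91 and 6 of 92 HFD cells. Genes that lead the Paneth-like cluster and a stem-like cluster differ between the diets, and the sort can set all shares, so no change of share is read from these clusters. Counted without clusters, cells with at least 3 Paneth markers at 10 TPM or more numbered 7 and 5 in the control sets and 25 and 20 in the HFD sets. The stem marker score differed by −0.01 (spread 0.128), the goblet score by 0.34 (spread 0.153), and scores of T cells, B cells, myeloid cells and stromal cells by 0.01 or less in size, as 0.006, −0.005, −0.004 and 0.004.

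Within stem-like and progenitor-like cells alone (87, 84, 76 and 80 cells), class II, Reg3 and lipid genes were again among those called. H2-Aa had a log2 fold change of −1.78 (SE 0.30) and Cd74 of −1.31 (SE 0.26, 439 ± 8.75 against 177.25 ± 15.1 TPM). The same 6 of 7 class II genes fell, all 7 fell over the list alone, and the median lay −1.52 from all genes (camera adjusted p = 3.57e-19, 0.210 with an estimated correlation). Reg3b (−5.71, SE 0.44) and Reg3g (−1.82, SE 0.32) fell. Fabp1 rose from 42.5 ± 18.3 to 449 ± 57.9 TPM (3.43, SE 0.27), Acaa1b by 2.19, and of 25 cholesterol synthesis genes Sqle (1.49), Sc4mol (1.49), Fdps (1.33) and Idi1 (1.13) rose and 21 did not pass (camera adjusted p = 2.83e-08, 0.210 with an estimated correlation). Scarb1 (1.81, SE 0.35), a lipoprotein receptor, Amd1 (1.81), an enzyme of polyamine synthesis, Nutf2 (1.55), Cenpk (1.54), a kinetochore protein, Gins1 (1.52), a replication factor, Lyz1 (1.51) and Ciapin1 (1.49) completed the 10 largest rises. S100g (−2.71), H2-Q8 (−2.39), Oplah (−2.38), Tk2 (−1.99), Cyp4a32 (−1.88), Nrn1 (−1.83) and H2-DMb1 (−1.46) were the remaining large falls. Of 22 unfolded protein response genes Sdf2l1 (1.19) and Calr (1.15) rose and 20 did not pass, with the median 0.46 above all genes (camera adjusted p = 1.08e-05, 0.210 with an estimated correlation). None of 40 S phase genes passed and 19 rose over the list alone (camera adjusted p = 1.09e-14, 0.210 with an estimated correlation).

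In this comparison 36 of 11622 genes were called, 20 higher and 16 lower, and 31 of them were also called over all cells. Itln1, at 1.24, was not among them (adjusted p = 0.328). The diets filled the stem-like clusters unevenly: cluster 2 held 49 control cells of 57, and cluster 1 held 43 HFD cells of 59. A test of whether the diet difference itself differed between the classes called 0 of 11623 genes by limma, with 712 at an unadjusted p under 0.05. With Rn45s left out of the total, 2 of the 36 were called, and in stem-like cells alone 1 was.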

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

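Chosen only after the data were seen were leaving Rn45s out, progenitor-like cells alone, stem-like cells alone for class II shares and all scores, the interquartile range of gene numbers for lists and scores, median-ratio scaling for lists, the block for class II shares, and for S phase and G2/M scores the block, pseudocount 0.1 and the filters on cells; the others were planned before. Replicate numbers are shared by the diets, but with 2 pairs nothing says that they pair the sets. Same-numbered sets deviated together with a correlation of 0.233 (0.198 without Rn45s), and with the replicate number as a block 5.44% of tested genes were called over all cells (635 genes), 7.37% in stem-like and progenitor-like cells (857), and 4.24% with Rn45s left out (514, of which 44.2% rose, with all 59 calls of the report among them). The 59 calls over all cells, 0.506% of tested genes, became 0.694% to 1.27% when 1 set was left out (0.789% without control 1, 1.27% without control 2, 0.840% without HFD 2), where the lone set is assumed to vary like the others. They became 0% with no filter on low values, 0.0857% (10 genes) with quantile normalization, 0.120% (14) with all cells, 0.155% (18) in the interquartile range of gene numbers, 0.310% (36) in stem-like and progenitor-like cells, 0.0514% (6) with no trend, 0.0495% (6) without Rn45s, and 0.272% (33) with cell-wise logs without Rn45s. Of the original 59, 51, 53, 34 and 52 were called with control 1, control 2, HFD 1 and HFD 2 left out, and 46 under median-ratio scaling. Calls lost without a filter, a trend or Rn45s went with a lower prior degrees of freedom, but not with cell-wise logs without Rn45s. Other causes were not tested. With 1 set left out, and with the block without Rn45s, 1 residual degree of freedom was left and the prior was infinite. Every gene then took the trend's variance, so calls kept or gained there say little about single genes. The 36 calls in stem-like and progenitor-like cells became 0.327% to 1.06% with 1 set left out (1.06% without control 2, 0.611% without HFD 1), 0.00866% (1) in stem-like cells, 0.0173% (2) in progenitor-like cells and 0.0166% (2) without Rn45s; without HFD 2, 14 rose and 24 fell. The 7 called lists became 5 to 12 (12 without control 2), 0 with an estimated correlation and 0 by fry; the class II list, at −1.62, had adjusted p-values of 0.211 and 0.0981 there, and between 2.70e-42 and 2.29e-10 under its other alternatives, where its median stayed below −1.35. Since fry tests a list against no change and not against the other genes, its results answer another question than those of camera. The class II score difference was −2.49 at pseudocount 0.1, −0.95 at pseudocount 10 and −1.86 without Rn45s. The S phase difference was 1.06 and 0.46 at those pseudocounts and 0.93 in stem-like and progenitor-like cells. The G2/M difference was −0.19 in progenitor-like cells and −0.12 in the interquartile range of gene numbers. The stem-like share differed by −18.7 to −8.15 points with 1 set left out (−8.15 without HFD 1), −24.9 at resolution 1.5 and −29.8 without cell cycle genes, where enterocyte-like clusters of mostly HFD cells formed (2, 3, 10 and 15 cells of control 1, control 2, HFD 1 and HFD 2, and 1, 6, 15 and 27); at resolution 0.5 no goblet-like or Paneth-like cluster formed. The enterocyte-like clusters took their name by small margins. Their enterocyte markers scored 3.16 against 2.96 in the other cells at resolution 1.5, and 3.16 against 2.95 without cell cycle genes. Stem markers in them were also above the other cells, at 6.71 against 6.69 and 6.83 against 6.67. Their cells thus left the stem-like share by the naming rule, with stem markers no lower than elsewhere. Sign changes were among genes and lists not called in the report. With 1 set left out, Lgr5 ranged from −0.30 to 0.17, Cpt1a from −0.013 to 0.21 and Pdk4 from −0.23 to 0.17, and in stem-like and progenitor-like cells from −0.35 to 0.086, −0.000130 to 0.22 and −0.12 to 0.11. Cpt1a was −0.046 by median ratios, −0.17 by quantiles, −0.10 without Rn45s with or without the block, −0.010 with cell-wise logs without Rn45s, and −0.089 without Rn45s in stem-like and progenitor-like cells. Pdk4 was 0.13 with cell-wise logs, 0.084 with these without Rn45s and 0.15 in progenitor-like cells, Olfm4 −0.046 with cell-wise logs without Rn45s, and Lgr5 0.021 in stem-like cells. List medians with 1 set left out ranged from −0.047 to 0.046 for class II transcription factors, −0.21 to 0.090 for class I, −0.063 to 0.28 for Notch, −0.060 to 0.19 for fatty acid synthesis, −0.46 to 0.47 for ribosomal proteins (lower with an adjusted p = 1.23e-05 without control 1, higher with 9.92e-05 without control 2), −0.12 to 0.23 for G2/M (higher with an adjusted p = 0.0241 without control 2) and 0.072 to 0.17 for antioxidant genes. Where the direction of a list's test turned, medians were 0.084 (class II transcription factors), −0.072 (fatty acid synthesis), −0.036 (ribosomal proteins) and 0.042 (antioxidant genes) by quantiles; −0.015 by median ratios, −0.025 without Rn45s and −0.026 by fry for class II transcription factors; 0.0093 without Rn45s for ribosomal proteins; −0.16 by fry for class I; −0.091 in stem-like and progenitor-like cells for Notch; and, in the interquartile range of gene numbers, 0.0054 for type I interferon, 0.085 for pattern recognition, 0.041 for fatty acid synthesis and −0.10 for G2/M (called lower, adjusted p = 0.0252). The cause of these turns was not tested. The medians given for fry are those of the report's own fit, since fry used the same values. Of 1250 values of named genes under alternatives, 823 kept direction and side of the threshold, 404 lost their call and 18 changed sign; 26 list values lost their call, 27 changed direction and 21 gained a call (antimicrobial, stem cell signature, ketogenesis, glycolysis, ribosomal and G2/M lists). Depth is unknown, so no limit of detection can be given for low genes.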

Other observations

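All tests of explanations here were chosen only after the result was seen, except those of the within-set relations of the class II score with cell cycle and stem markers. Goblet-like and Paneth-like cells held class II transcripts at these levels. The 12 goblet-like control cells had a mean class II score of 3.89 and all 12 held Cd74, against a score of 2.19 in 13 goblet-like HFD cells, of which 12 held Cd74. The 14 Paneth-like HFD cells had a score of 0.85 and 6 of them held Cd74; only 1 Paneth-like cell came from the control sets. These cells are few and the differences were not tested. The goblet-like cluster also depends on the clustering: at resolution 1.5 and without cell cycle genes only 13 cells were goblet-like (4, 2, 5 and 2 in control 1, control 2, HFD 1 and HFD 2), so some of the 25 may not be goblet cells.

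Across cells within a set, the class II score went with Reg3g at Spearman's rho of 0.246 and 0.217 in the control sets and 0.030 and 0.117 in the HFD sets. Fabp1 had a negative rho with the class II score in each set, −0.140 and −0.085 in the control sets and −0.268 and −0.347 in the HFD sets. Given the number of genes detected, the values for Fabp1 were −0.164, −0.089, −0.174 and −0.344. Cells of a set are not independent replicates, and no p is given for these relations. A hypothesis that cells with more class II transcripts cycle less asked for a rho below −0.1 with the S phase score in all 4 sets; the highest was 0.167, in control 1, and the others were 0.058, −0.018 and −0.033. A hypothesis that such cells hold more stem cell markers asked for a rho above 0.1 in all 4 sets; the lowest was −0.092, in HFD 1, and the others were −0.035, −0.061 and 0.048. With the G2/M score, which the first hypothesis did not use, rho was 0.139, −0.097, −0.264 and −0.038 in control 1, control 2, HFD 1 and HFD 2. Given the number of genes detected, these values were 0.093, −0.032, −0.097 and −0.003, and those for S phase 0.13, 0.168, 0.156 and −0.004. Neither hypothesis was borne out.

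The lower class II transcripts in the HFD sets could come from scaling, from immune cells or from another mix of cells. With Rn45s left out of the total the list median was −1.61 relative to all genes (SD over genes 0.32). Taking away the median of all genes removes any shift common to them, so that value cannot test scaling. The per-cell class II score has no median of other genes taken away, although TPM is itself a share of the total. Rn45s took more of TPM in the control sets on average (39.1% and 24.6% against 26.9% and 18.6%), which lowers other genes there. Leaving it out could thus on average only widen the fall, so the score is no separate test of scaling. The difference went from −1.69 with TPM as deposited to −1.86 (spread 0.23) without Rn45s. By these shares, scaling by Rn45s works against the fall. The single-gene calls were lost with Rn45s left out, where the moderating prior fell from 21.3 to 7.21 degrees of freedom. All 59 calls were made on the same values with the replicate number as a block, although nothing says that the numbers pair the sets. That fit called 514 of 12124 genes with 1 residual degree of freedom and an infinite prior, so every gene took the trend's variance. It therefore says little about whether the 59 hold without Rn45s. The cause of the loss was not tested further. In the control sets, 94.02% of cells held Cd74 with Ptprc under 1 TPM, which argues against immune cells, and the score difference was −1.64 (spread 0.47) in the class where it was smaller, which argues against the mix of these classes. Enterocyte-like clusters of mostly HFD cells, which formed only under other clusterings, were not tested as a source. Only 3 splits of the 4 sets exist, too few for a share under 0.05. With TPM as deposited, the real split called 59 genes, the highest other split 0, and 1 split reached the real count. There limma's unadjusted p was under 0.05 for 1294 genes by diet and 759 by replicate 1 against replicate 2. With Rn45s left out, these were 784 by diet and 1381 by replicate number, with 6 and 0 called. By that count the split by diet was then not the strongest. A biological effect of diet on class II expression stays open as a hypothesis, as do differences between mice, sorts or plates, since the labels do not say which of these the sets share.

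Paneth cell transcripts, higher in the HFD sets, could come from the 14 Paneth-like HFD cells alone or from reads shared between defensin copies. In stem-like and progenitor-like cells the Paneth score still differed by 0.28 (spread 0.022), with 2 Paneth markers called, which argues against those cells as the whole cause, although the difference over all cells was 0.69. The 6 tested Paneth markers outside the defensin family had a median of 2.14 above all genes with an SD of 2.13 between them, and 2 were called, so shared reads cannot be told apart from a rise of each defensin. Doublets, RNA from neighbouring Paneth cells and a wider gate in the HFD sorts were not tested.

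S phase genes, higher in the HFD sets, could come from more progenitor-like cells, from scaling or from cells with more genes detected. Within stem-like cells the score difference was 0.90 (spread 0.23), which argues against the share of progenitor-like cells, although the diets filled the stem-like clusters unevenly. With Rn45s left out it was 0.70 (spread 0.27), which argues against scaling. Among cells in the interquartile range of gene numbers it was 0.82 with a wide spread of 0.57, which argues only weakly against gene detection, and there control 2, at 4.06, came close to HFD 1, at 4.13. The G2/M score within stem-like cells differed by 0.16, less than its spread of 0.19, and Mki67 was at 1 TPM or more in 60.2% and 59.3% of control cells and 73.6% and 53.3% of HFD cells, so neither goes clearly with more cycling. The score of the 12 proliferating progenitor markers, Mki67 and S phase genes among them, was 4.43 and 4.49 in the control sets and 5.19 and 4.87 in the HFD sets, 0.57 higher with a spread of 0.165, and 0.75 higher within stem-like and progenitor-like cells. More replication in HFD stem cells is a hypothesis left open.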
